A study of Homo sapiens with 12 samples.

How the data were processed

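The samples were 12 total RNA preparations from A375, a human melanoma cell line, carrying 1 of 2 doxycycline-inducible short hairpin RNAs (shRNA #31 or #33) against MELK, a serine/threonine kinase of dividing cells. The cells had received doxycycline, which switches the shRNA on, or vehicle for 3 days, per the labels' protocols. Each of the 4 groups held 3 arrays, taken from the sample titles. The RNA was hybridised as biotin-labelled cRNA to an Illumina expression array, per the labels. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. All 12 arrays shared 1 chip. The vehicle samples lay on the first 6 lettered positions and the doxycycline samples on the last 6, so position and treatment cannot be told apart by the design.

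The deposited table gave, for each of 48107 probe rows and each array, a bead intensity on a linear scale and a detection p-value. The detection p-value is the share of negative control probes at least as bright as the row. The scanner software is not given in the sources used here. The intensities had not been normalized or background-subtracted, as seen from their values. The authors also deposited a value table on the log2 scale. Its columns were the quantile-normalized log2 of the same intensities, with a largest difference of 0.0011 from a recalculation, and its 12 missing values were the lowest value of each array. Scale, centring and direction of that table are therefore known from the values.

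Gene names came from the platform annotation supplied for the probe identifiers. It gave 1 symbol to 30113 rows, several to 8 and none to 17986. Of its gene identifiers, 47 were not found in the RefSeq gene table (assembly GRCh38.p14), and 0 symbols needed an update. No row with several symbols was named.

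Intensities were background-corrected, offset by 16 and quantile-normalized with neqc in limma 3.58.1 under R 4.3.3. The background was estimated from the detection p-values, because no control probes were used here. Rows with a detection p under 0.05 on at least 3 arrays were kept, which left 22945 rows. A gene was represented by its brightest row, giving 11497 genes. A linear model with the 4 group means was fitted to all 12 arrays (lmFit and eBayes, 7.23 prior degrees of freedom). The comparisons were doxycycline against vehicle in each line, the mean of both effects, their difference (sh33 minus sh31), and sh33 vehicle against sh31 vehicle. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Folds are on the offset log2 scale, which understates changes of dim rows. A row undetected on all arrays of a group was given a bound in place of a fold.

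Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry. Of 27 lists, those on NF-kB targets, mitosis, DNA replication, p53 targets, interferon-stimulated genes, MAPK output and melanocyte genes are reported singly, and 20 further lists as counts. A further list is named only where it had the smallest camera p of a comparison. The groups, the tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined. That rule named MELK and 9 NF-kB-related symbols, the 12 highest and 12 lowest genes called in both lines and for the mean effect without overlap between arrays, and the 5 highest and 5 lowest of each other comparison. Fewer are given here, as the deposited labels, because the identifiers failed the checks described next.

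Whether the identifiers follow the intensities was checked after the values had been seen. The levels of rows under 1 symbol or 1 accession were correlated, with 100000 permutations per test. Detection was compared between gene classes, and the identifier column was tried at every offset in 4 orders. On simulated labels that followed the values, the same statistic gave a correlation of 0.515, and 0.00145 once they were shuffled. The size of 0.515 was planted, by giving gene levels and row noise the same spread. It checks the statistic and does not show what correct labels would give in these data. Counts over probe rows, which use no gene name, are therefore given beside the counts over genes.

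The model was tested on simulated data made from the row means and spreads, with 200 changed genes among 11497. The noise was normal and independent between genes, unlike that of real arrays. The 30 genes labelled as cytosolic ribosomal proteins were also shifted by 0.2 in the sh33 doxycycline group. Their calls were not counted as false but entered the total of calls. For a planted log2 change of 0.5, 51% of the genes were recovered in the sh31 comparison, 50% in the sh33 comparison and 82% for the mean effect. For a planted change of 1 these shares were 95%, 98% and 100%. False calls numbered 10, 9 and 14, or 6.4%, 5.7% and 7.1% of all calls, slightly above the nominal 5%. The number of arrays limits the precision, with a median standard error of 0.12 on the log2 scale in a line and 0.09 for the mean effect. Alternatives covered background and normalization, the value table, the detection filter, probe summary, blocking, array weights, subsets of arrays, a fold minimum, prior settings and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.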

Results

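Gene expression was measured in A375 melanoma cells carrying an inducible shRNA against MELK. There were 2 lines, named here sh31 and sh33 after their shRNAs, each with 3 vehicle and 3 doxycycline arrays after 3 days. The design asks which transcripts change when the shRNA is induced, and whether both shRNAs give the change. Mean intensity per array lay between 234.4 and 339 units, and 19533 to 20903 of 48107 rows were detected per array. Doxycycline arrays averaged 290.7 units and vehicle arrays 319.5, a difference of -28.86 (exact permutation test, two-sided, p = 0.0693, n = 6 per treatment). The dimmest array was replicate 1 of the sh31 doxycycline group. Correlations between arrays over the 11497 tested genes ran from 0.988 to 0.996.

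The targeted gene was read first. The platform carried 2 rows labelled MELK. The row ILMN_1731184 was detected on 0 of 12 arrays, with a lowest detection p-value of 0.0515. The row ILMN_2212909 was detected on 12 of 12 arrays, close to background. In the sh31 line its normalized log2 intensity was 5.43 ± 0.08 (SD, n = 3) with vehicle and 5.23 ± 0.06 (SD, n = 3) with doxycycline. In the sh33 line it was 5.36 ± 0.14 and 5.19 ± 0.23 (SD, n = 3 each). The log2 fold change was -0.20 (SE 0.12, limma adjusted p = 0.636) in the sh31 line and -0.17 (SE 0.12, limma adjusted p = 0.535) in the sh33 line. For the mean of both lines it was -0.19 (SE 0.08, limma adjusted p = 0.314). MELK was named beforehand, and its limma p-values without adjustment were 0.111 (sh31), 0.165 (sh33) and 0.0413 (mean). In the authors' value table, which has no background correction, the log2 fold changes were -0.066 (sh31), -0.054 (sh33) and -0.060 (mean). With the background correction, leaving out sh33_dox replicate 2 moved the sh33 value to -0.046. The row labelled MELK thus passed the adjusted threshold in neither line, and knockdown could not be established from it.

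**Figure D1:**
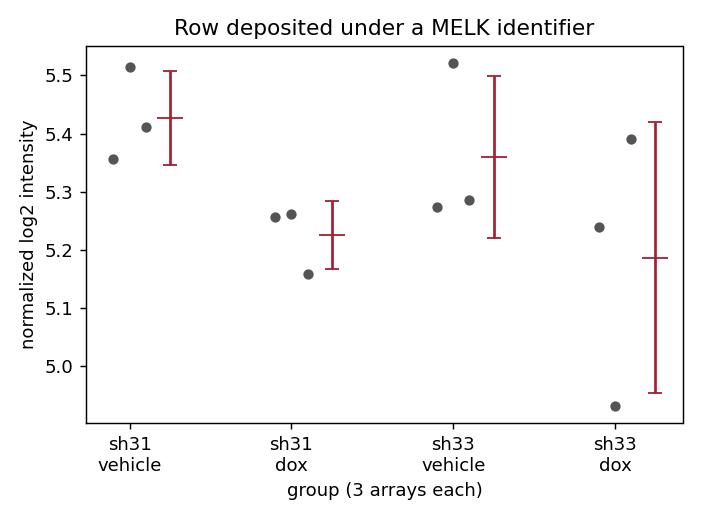
Normalized log2 intensity of the row ILMN_2212909, labelled MELK, on each of the 12 arrays by group; grey points are arrays and red bars are the mean and SD of 3 arrays. The group means lie between 5.19 and 5.43, and no comparison of doxycycline with vehicle passed the threshold.

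The labels of the other rows were then checked, since a row that does not hold the named gene tells nothing about it. For 6691 genes with more than 1 row, the levels of the first pair of rows were uncorrelated (Pearson r = -0.013, permutation p = 0.28). Rows designed against the same accession were no closer (r = -0.012 over 5698 pairs). By contrast, the level of a row in the sh31 arrays and in the sh33 arrays correlated at 0.9986. These correlations are across genes or rows, which are not independent replicates. Restricting to 698 pairs detected on all 12 arrays left r at -0.018.

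**Figure D2:**
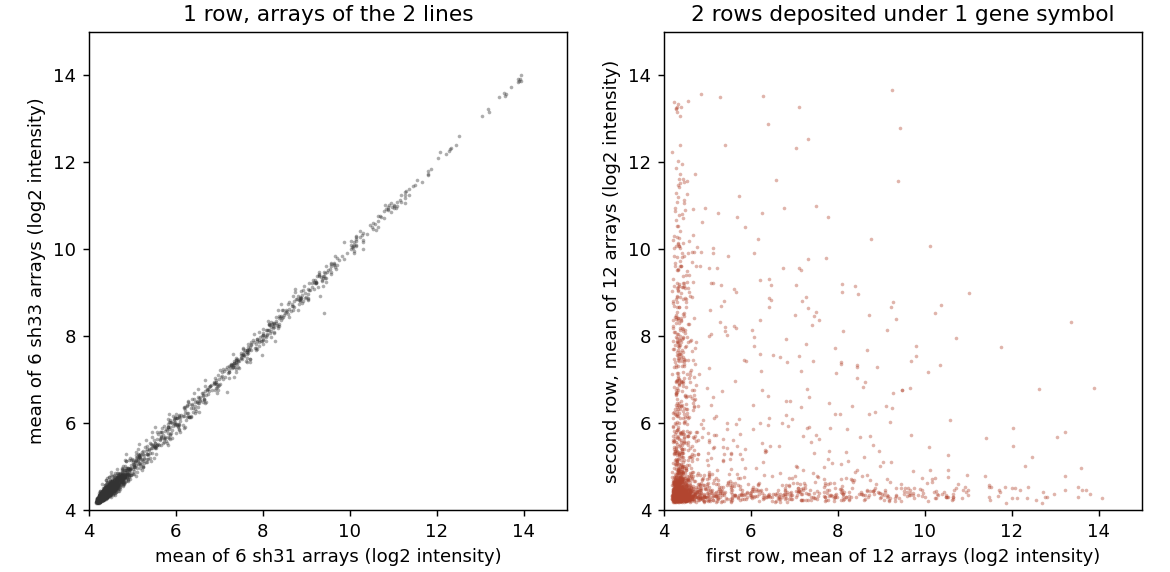
Mean log2 intensity of 2000 randomly drawn rows in the 6 sh31 arrays against the 6 sh33 arrays (left), and of 2000 pairs of rows deposited under 1 gene symbol, each averaged over 12 arrays (right). Row levels repeat between the lines (r = 0.9986 over all rows), while rows under 1 symbol are unrelated (r = -0.013 over all 6691 pairs).

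Detection was also compared between gene classes by label. Of 107 rows labelled with cytosolic ribosomal proteins, which growing cells make in abundance, 39.3% were detected (exact 95% interval 30 to 49.2). Of 437 rows labelled with olfactory receptors, which are silent in most tissues outside the nose, 49.9% were detected (45.1 to 54.7). The difference did not pass the threshold (Fisher's exact test, two-sided, p = 0.052), and all rows with a symbol gave 47.6%. Rows labelled with 7 genes made in abundance by most growing cells (GAPDH, ACTB, EEF1A1, LDHA, VIM, TUBA1B and RPS3), chosen after the data were seen, numbered 17. Of these, 3 were detected on all 12 arrays, 7 on some and 7 on 0. The rows labelled ACTB were detected on 12, 0 and 12 arrays, those labelled EEF1A1 on 0, 12, 0 and 1, and those labelled GAPDH on 3, 11 and 0. The deposited value table held the same pairing of identifiers and ranks. Symbols below are therefore the deposited labels of rows, and no change is assigned to the gene of that name.

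Rows did change with doxycycline in both lines. In the sh31 line 78 genes were called, 11 higher and 67 lower, which was 123 of 22945 rows when every row was tested. In the sh33 line 327 genes were called, 137 higher and 190 lower, and 527 rows. Changes of at least 2-fold were seen in 24 called rows of the sh31 line and 52 of the sh33 line. The count in the sh31 line was 125 (33 higher and 92 lower) with the authors' value table, and 43 without sh31_vehicle replicate 2 and 47 without sh31_vehicle replicate 3. In the sh33 line the value table gave 496, while leaving out sh33_vehicle replicates 1, 2 or 3, or sh33_dox replicate 3, gave 195, 181, 195 and 214.

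For the mean effect of both lines 319 genes were called, 125 higher and 194 lower, and 480 rows. Of these genes, 43 were also called in each line with the same direction, 5 higher and 38 lower. All 43 were without overlap of the arrays in each line, so that condition removed no gene and adds no support. In 1 comparison of 3 against 3 arrays chance alone leaves 10% of genes without overlap, and fewer in both lines with 1 direction. Calls in both lines with 1 direction numbered 70 (13 higher and 57 lower) with the value table. With normexp at an offset of 50 they numbered 65 (11 higher and 54 lower). The lowest of the 43 was the row labelled TMEM263, with a log2 fold change of -2.65 (SE 0.09, limma adjusted p = 7.47e-11). The row labelled PDPK1 followed at -2.24 (SE 0.07, limma adjusted p = 5.29e-11). The rows labelled OTOP1 and OPA3 followed at -1.65 and -1.55. The highest was the row labelled C11orf16, for which no mean fold is given because it was detected on 0 of 3 vehicle arrays of the sh33 line. The rise there was at least 5.31-fold (limma adjusted p = 2.83e-08). In the sh31 line, where 1 of 3 vehicle arrays detected it, its log2 fold change was 2.44 (SE 0.14, limma adjusted p = 5.75e-08), a size that is uncertain because the vehicle level lay close to background. In the authors' value table the rise of this row was at least 2.03-fold in the sh33 line, with a log2 fold change of 0.99 in the sh31 line, and with normexp at an offset of 50 these were 2.55-fold and 1.33. The next was the row labelled STYX, at 0.84 (SE 0.09, limma adjusted p = 7.25e-05). The other sizes depended on the background correction too: in the authors' value table, which has none, the mean effects were 0.31 for STYX, -1.88 for TMEM263, -1.45 for PDPK1, -0.78 for OTOP1 and -1.13 for OPA3. With the mean of a gene's rows PDPK1 stood at -1.09 and OPA3 at -0.45, but that mean joins rows with unrelated levels and tells little about the row named. Without sh33_vehicle replicate 3, 212 genes were called for the mean effect.

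Both lines shared a larger part of their calls than independent lists would. Called in both were 38 lower genes, where independent lists give 1.1, and 5 higher genes, where they give 0.13. A further 2 were called in opposite directions. The lines share no control arrays. Across all genes the effects correlated at Pearson r = 0.269 and Spearman 0.17, and at Pearson 0.231 without the 4 genes of largest change. Over probe rows 63 lower and 7 higher rows were shared.

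**Figure D3:**
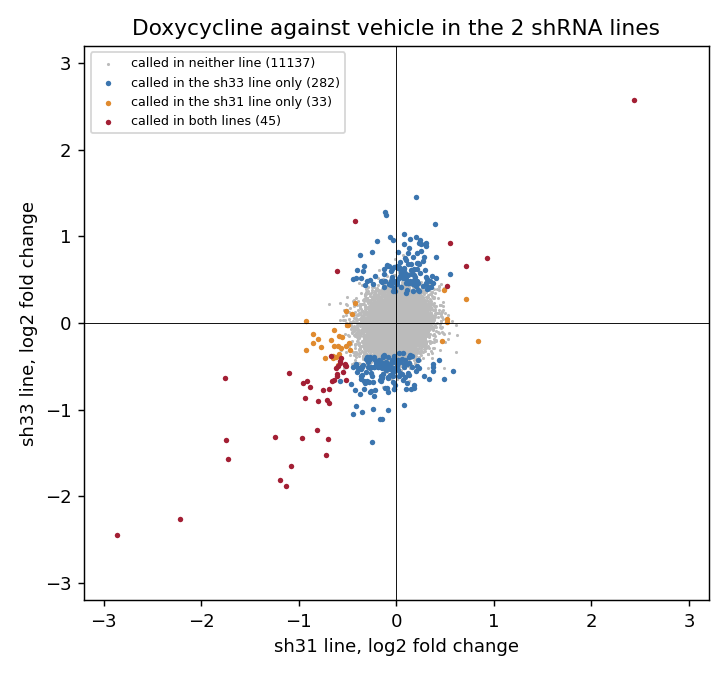
Log2 fold change of doxycycline against vehicle in the sh31 line (horizontal) and in the sh33 line (vertical) for 11497 genes as labelled in the deposited table, coloured by the line in which each was called. The 45 genes called in both lines are 38 lower in both, 5 higher in both and 2 in opposite directions.

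The effects of doxycycline differed between the lines for 39 genes, 22 more positive in the sh33 line and 17 more negative, by the interaction test. The row labelled IKBKB had the most positive difference, 1.60 (SE 0.13, limma adjusted p = 2.55e-05), with log2 fold changes of -0.42 in the sh31 line and 1.18 in the sh33 line. The row labelled FRAT1 followed at 1.39 (SE 0.23, limma adjusted p = 0.0155). The most negative differences were those of the rows labelled OR5AS1, at -1.13 (SE 0.20, limma adjusted p = 0.0213), and IGFBP6, at -1.13 (SE 0.18, limma adjusted p = 0.0119). The call of OR5AS1 was lost, at adjusted p from 0.0609 to 0.0765, in 8 of the 12 fits without 1 array: replicates 2 and 3 of sh31_vehicle, of sh31_dox and of sh33_dox, and replicates 1 and 3 of sh33_vehicle. It was also lost with no detection filter (0.0576) and with median centring (0.0536), and its size was -0.46 in the value table. The call of FRAT1 was lost with median centring (0.0743), and its size was 0.58 in the value table. It was also lost with the mean of its rows (0.0933), which tells little, since rows under 1 symbol had unrelated levels. The value table gave 116 genes for this difference. Leaving out sh31_vehicle replicate 3 or sh33_vehicle replicate 2 gave 22. Of 100 splits of the arrays between the lines, the real one included, 9 gave at least 39 genes. Some of these splits keep the doxycycline arrays of the lines apart, so the share decides nothing about chance.

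Without induction the lines did not differ in any gene that limma called. The count was 0 of 11497 genes, with 450 (3.91%) at an unadjusted p under 0.05, and 1 of 22945 rows when every row was tested.

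The gene lists could be tested only by label. Since labels did not follow levels, the lists hold rows of unknown genes. Calls, or their absence, therefore tell nothing about the pathways named. In all 27 lists 450 of 859 members were measured, and camera called 0 lists in either line, for the mean effect or for the difference, with the preset or an estimated correlation. The smallest adjusted p from camera was 0.592 in the sh31 line, 0.813 in the sh33 line, 0.466 for the mean effect and 0.651 for the difference, and 1 list in each had an unadjusted p under 0.05. In the sh33 line and for the mean effect that list was glycolysis and hypoxia response. Its median log2 fold change was -0.106 (camera unadjusted p = 0.0361) and -0.095 (0.0173). In the sh31 line and for the difference the list was MAPK output. The median log2 fold change of MAPK output was 0.08 in the sh31 line (camera unadjusted p = 0.0219) and -0.05 in the sh33 line (0.455). For the difference it was -0.13 (0.0241). For the mean effect the median log2 fold change was 0.02 over 20 rows labelled as NF-kB targets (camera adjusted p = 0.891; their mean was -0.0092) and 0.01 over 30 mitosis rows (0.811). It was 0.06 over 25 DNA replication rows (0.755), -0.0027 over 17 p53 target rows (0.847) and -0.02 over 22 interferon-stimulated rows (0.803). It was 0.03 over 16 MAPK output rows (0.803) and -0.0093 over 16 melanocyte rows (0.952). Of these members the mean effect called 1 mitosis row, higher, and 2 DNA replication rows, 1 higher and 1 lower. Adjusted over the list alone, it called 2 mitosis rows and 2 replication rows. The fry test called 0, 3, 5 and 0 lists in the sh31 line, the sh33 line, the mean effect and the difference, and 2, 13, 8 and 5 for change in either direction. It does not compare a list with other genes, so a few changed rows can give a call. In the same order, 0.444%, 2.44%, 2% and 0.667% of list members were called. The shares of all genes were 0.678%, 2.84%, 2.77% and 0.339%. Of 10 symbols fixed for the target and the NF-kB pathway, 4 labelled a measured row (MELK, NFKB2, TNFAIP3 and IL6) and 0 were called, with the same limit.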

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

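The tests of the row labels, of the strength of knockdown and of doxycycline itself were chosen after the results were seen; the tests of spread, the dim array, brightness, chip position and other splits were set beforehand.

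The effects of doxycycline differed between the lines for 39 genes by the interaction test. Of 100 splits of the arrays between the lines within a treatment, the real one included, 9 gave as many, and the highest of the others gave 88. Some of the splits keep the doxycycline arrays of the lines apart and move only vehicle arrays, between which no gene was called. Such splits retain any real effect of the line, so the share cannot decide on chance, which stays open. The rows flagged by this difference were those labelled IKBKB (1.60), FRAT1 (1.39), OR5AS1 (-1.13) and IGFBP6 (-1.13). Of these, OR5AS1 lost its call in 8 of the 12 fits without 1 array and FRAT1 with median centring (limma adjusted p = 0.0743). FRAT1 also lost it with the mean of its rows (0.0933), which tells little, since rows under 1 symbol had unrelated levels. A signal also lay in rows the gene counts do not use: of 8603 detected rows with no symbol, 170 (1.98%) were called for the mean effect, against 2.16% of the rows with a symbol.

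Rows deposited under 1 gene symbol had unrelated levels. The correlation farthest from 0 among 10 equal parts of the table was 0.081 for rows of 1 accession, so identifiers attached to the wrong rows over the whole table may explain it. The identifiers themselves keep their order, as 4744 neighbouring rows share a symbol against 1 after shuffling. Noise of dim rows is argued against by the correlation of -0.018 among rows detected on all arrays. A constant shift or reversal of the identifier column, or a sort by identifier number, is argued against by a highest rank correlation of 0.061 over all offsets. Sorts by another key and shifts of only part of the table were not tried. No biological explanation was tested, and the true pairing stays unknown.

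More genes were called in the sh33 line (327) than in the sh31 line (78). A larger spread in the sh33 arrays is argued against, as their median residual variance was 0.95 times that of the sh31 arrays. The dim sh31 doxycycline array is argued against too: without it 52 genes were called in the sh31 line, against 181 for the lowest sh33 count with any array left out. A different strength of the knockdown stays open, because the difference of 0.0279 (SE 0.168) in the row labelled MELK tells nothing while labels do not follow levels.

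Most genes called in both lines fell. Within groups, the slope on array brightness gave a share of 0.0065 (SE 0.0113) of their mean fall of -0.94. The values had already been quantile-normalized, and calls in both lines favour genes with a small spread within groups. A small share was therefore likely beforehand, and it does not decide whether the dimmer doxycycline arrays play a part. A linear trend along the chip positions gave a share of 0.014 (SE 0.0328), with the same limit from the choice of genes. Nor is a step between the first 6 and last 6 positions covered, as the treatments share neither. Doxycycline itself, or any induced shRNA, cannot be told apart from loss of MELK, because 0 samples came from a line without a MELK shRNA. Loss of MELK stays open and untested.

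For the mean effect (319 genes) 1 of 100 splits of the arrays within lines, the real one, reached that count, and the highest other gave 91. The count of 43 genes called in both lines with 1 direction was likewise reached by the real split alone (1 of 100 splits, highest other 2). The 100 were drawn from 200 possible splits, so 1 of 100 was the lowest share that could be found. Most other splits mix vehicle and doxycycline arrays in a group, which adds any real effect to the spread and lowers their counts. The gap to the other splits is therefore no measure of the size of an effect. If nothing differed between the treatments, the arrays of a line would be exchangeable. The share of 1 of 100 thus argues against chance for both counts, among these samples. It does not bear on chip position or on whether replicates were separate cultures. The correlation of 0.269 was reached by 2 of 100 splits, the real one included, and the highest other, 0.277, lay above it. A count of 0 is reached by any split, so the splits decide nothing on the called lists (100 of 100, highest other 1) or on the vehicle comparison (10 of 10, highest other 0). Within 1 line only 10 splits exist, too few for a share under 0.05. The real counts of 78 and 327 stood against 0 in the highest other split (1 of 10 each).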

How the results depend on the processing

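Of 545 values under 28 other settings, 493 kept their direction and side of the threshold, or stayed within 1.5 times or the spread; 40 moved, 12 lost a call and 0 reversed. The cause of the moves was not tested, except that testing every row adds rows, a fold minimum removes genes, and 6 arrays leave fewer degrees of freedom. With log2 and quantile normalization and no background correction, and with the value table, the counts were 125 (sh31), 496 (sh33), 116 (difference) and 70 (both lines), and the correlation was 0.348. With normexp at an offset of 50 they were 118, 508, 119 and 65, and 0.328. Median centring gave 51 (sh31), 20 (difference) and a correlation of 0.362. Detection on all 12 arrays at p under 0.01 gave 86 genes for the difference and a correlation of 0.33. Array weights gave 63 and eBayes with trend and robust 109 for the difference. At least 1.5-fold left 150 (sh33) and 51 (mean). Every row tested gave 123, 527, 480, 70 (difference), 1 (vehicle) and 70 (both lines). The 6 sh31 arrays alone gave 47.

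Leaving out 1 array at a time gave 43 to 82 genes (sh31), 181 to 340 (sh33), 212 to 300 (mean), 22 to 43 (difference), 31 to 42 in both lines, and a correlation of 0.223 to 0.277. The vehicle comparison and the lists stayed at 0. The log2 fold change of the row labelled MELK ran from -0.23 to -0.16 (sh31), -0.28 to -0.05 (sh33) and -0.24 to -0.12 (mean), with no call. The call of the row labelled OR5AS1 was lost in 8 of the 12.

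Replicate numbers did not clearly pair the samples, judged by correlating deviations from the group means. Of 18 same-number pairs 2 correlated above 0.1, from -0.24 to 0.25, and 3 of 12 arrays correlated best with their own number. Between vehicle and doxycycline, replicates 1, 2 and 3 gave 0.252, 0.0705 and 0.0966 in the sh33 line. In the sh31 line they gave -0.188, -0.14 and 0.0555. With the number as a block, the counts were 59 (sh31), 263 (sh33), 248 (mean), 33 (difference), 0 (vehicle) and 36 (both lines). Signal over background limits the dim rows: 22945 of 48107 rows passed detection.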

Other observations

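If the labels followed the transcripts, a called row and another row of the same gene would move together. Each called row was compared with the mean change of the other detected rows under its symbol. For the mean effect, 55 of 112 called rows (49.1%, exact 95% interval 39.5 to 58.7) moved in the same direction as that mean. In the sh33 line the count was 59 of 120, and in the sh31 line 12 of 26. Over 1585 pairs of detected rows the mean effects correlated at -0.025 across genes (permutation p = 0.31).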
